A study of Mus musculus with 6 samples.

How the data were processed

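RNA was sequenced from 6 mouse tumor libraries, 3 labelled CdGAP wt/wt and 3 labelled CdGAP fx/fx, all from tumors of mice carrying the NIC transgene. Per the labels' protocols, total RNA was extracted with TRIZOL, cleaned on RNeasy columns and made into libraries with standard Illumina methods, on an Illumina HiSeq instrument. The label of each library gave its genotype and its replicate number, and the libraries are called wt1, wt2, wt3, fx1, fx2 and fx3 here.

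The deposited values were whole-number counts of read pairs per gene, not normalized. Per the file headers, the counts were made by the authors with featureCounts 1.6.0 against the Ensembl release 93 annotation of GRCm38. The submitters' processing notes name FastQC 0.11.5, STAR 2.5.1b, featureCounts 1.4.6, DESeq2 1.12.3 and DESeq, with the build GRCm38, so the featureCounts version differs between the notes and the headers. Per the file headers, both ends of a pair had to be aligned, chimeric pairs were left out, and strand option 2 (reverse-stranded) was set. No option to count reads with several alignments appears in the headers, so near-identical genes such as the globin, histone and mast cell protease families can lose reads or share them, and their values are less certain. Strand-aware counting separates a gene from an antisense partner only as far as the library kit kept strand, and the kit is not given in the sources used here.

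Each file held 54232 gene identifiers. GENCODE M21, also on GRCm38, gave a symbol and a gene type for 54165 of them, and the other 67 kept their identifier. All rows named a gene (0 rows did not), so all counts entered the library sizes. Coordinates are those of the count files on GRCm38, counted from 1. Total counts were 45613269 in wt1, 42373196 in wt2, 46460750 in wt3, 53606276 in fx1, 36732137 in fx2 and 42955133 in fx3. At these depths 3 counts, the upper limit that a count of 0 allows, correspond to between 0.056 and 0.0817 CPM (counts per 1000000 counts), which covers counting error only.

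Genotypes were compared with edgeR 4.0.16 in R 4.3.3: genes past filterByExpr, TMM normalization, the quasi-likelihood test with robust=TRUE, 2-sided, and Benjamini-Hochberg adjustment, with an adjusted p under 0.05 as the threshold. Fold changes are log2 of fx/fx over wt/wt. CPM values use TMM-scaled library sizes, and errors are SDs over 3 libraries unless an SE is named. Arhgap31 was also compared by an exact 2-sided permutation test of log2 CPM (prior count 2) over the 20 orderings of the 6 libraries, which cannot give a p under 0.1.

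Gene lists, 47 in number with 775 genes, covered expression programs, sample quality and the cell types that a mammary tumor could hold. The 44 lists with at least 5 measured members were tested with limma 3.58.1 camera on log2 CPM with a preset inter-gene correlation of 0.01, and repeated with the correlation estimated per list and with fry. Members were counted after adjustment over all genes and adjusted over the list alone. Genes within 10 Mb of Arhgap31 were compared with all others by a 2-sided Fisher's exact test of called against not called.

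The lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule named Arhgap31; the 10 highest and 10 lowest protein-coding fold changes among genes past the threshold with separated genotypes and a mean of at least 5 CPM in the higher genotype, skipping near-identical paralogs, pseudogenes, immunoglobulin segments and predicted genes; up to 4 members of each list past the threshold, or, where a list passed with fewer than 2 such members, its 2 members with the smallest p; the genes Erbb2, Cdh1, Zeb2, Snai1, Snai2, Vim, Tln1, Cdc42, Rac1, Tgfb1 and Vegfa in any case; and, with fewer than 10 genes past the threshold, the 10 with the smallest unadjusted p. Because edgeR called 0 genes, the same extremes were also taken from the DESeq2 1.42.0 calls, which was decided after the data were seen, as was the description of chromosome medians. Some genes and a list that the rule or the tests cover are not reported here.

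Chromosome medians are the median over protein-coding genes with a mean log2 CPM over 3 of each library's log2 CPM minus the wt/wt mean, per chromosome, per 20 Mb bin with at least 15 genes, or per 5 Mb bin with at least 5 genes. A correction for GC content and transcript length used a loess fit (span 0.5, degree 1) on the longest GENCODE transcript, and 99.9% of tested genes had both values.

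The steps were tested on simulated counts with this comparison's means, dispersions and library sizes, 200 genes having been changed. Among 16466 simulated genes, edgeR recovered 2.06% of 2-fold and 53.7% of 4-fold changes, and 11.7% of its calls were false. DESeq2 recovered 13% of 2-fold and 74% of 4-fold changes among 16752 simulated genes, and 25.6% of its calls were false. A 2-fold shift of the endothelial list was recovered with adjusted p = 6.1e-13 while 1 other of the 44 lists was also called. Correlation between genes was not among the simulated properties. In the real data the estimated correlation of this list was 0.75. The recovery of the list therefore does not test camera with the preset correlation on lists whose members vary together. A planted chromosome 4 shift of -0.5 came back as -0.46 in the median of that chromosome, in a step with 9990 genes over all chromosomes.

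Alternatives were DESeq2 size factors, no filter on low counts, the replicate number as a block, protein-coding genes only, robust=FALSE, DESeq2, limma-voom with quality weights, other thresholds, other windows around Arhgap31 and each library left out in turn. No library pair agreed within sampling noise: the lowest chi-square per degree of freedom between any 2 libraries was 146.4, so all 6 were kept as separate samples. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 joined the files and drew the plots.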

Results

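Tumors were taken from NIC mice, in which the mouse mammary tumor virus promoter drives an activated ErbB2 (Neu) receptor together with Cre recombinase in mammary epithelium. CdGAP, the product of Arhgap31, is a GTPase-activating protein that switches off the small GTPases Cdc42 and Rac1. In fx/fx mice both copies of the gene carry sites that Cre can recombine, so the series asks how tumor gene expression differs when CdGAP can be deleted in the cells that express the oncogene. There were 6 libraries, 3 wt/wt and 3 fx/fx, with between 36732137 (fx2) and 53606276 (fx1) counts each. Protein-coding genes held between 97.7% and 98.2% of counts and mitochondrial genes between 1.81% and 2.93%. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these samples.

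Arhgap31 (ENSMUSG00000022799, chromosome 16, 38598340 to 38713274, minus strand, GRCm38) was lower in every fx/fx library than in every wt/wt library. It measured 664, 433 and 549.8 CPM in wt1, wt2 and wt3, and 156, 44.1 and 116 CPM in fx1, fx2 and fx3. The means were 549 ± 116 and 105 ± 56.5 CPM (SD, n = 3 each), a 5.22-fold lower level in fx/fx (log2 fold change -2.38, SE 0.45). The exact 2-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. The edgeR adjusted p was 0.153, which did not pass, and the DESeq2 adjusted p was 4.7e-05, which did. Counts were summed over the whole gene, so the recombined exon itself was not analysed here, and transcripts from cells without Cre remain in the total.

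**Figure D1:**
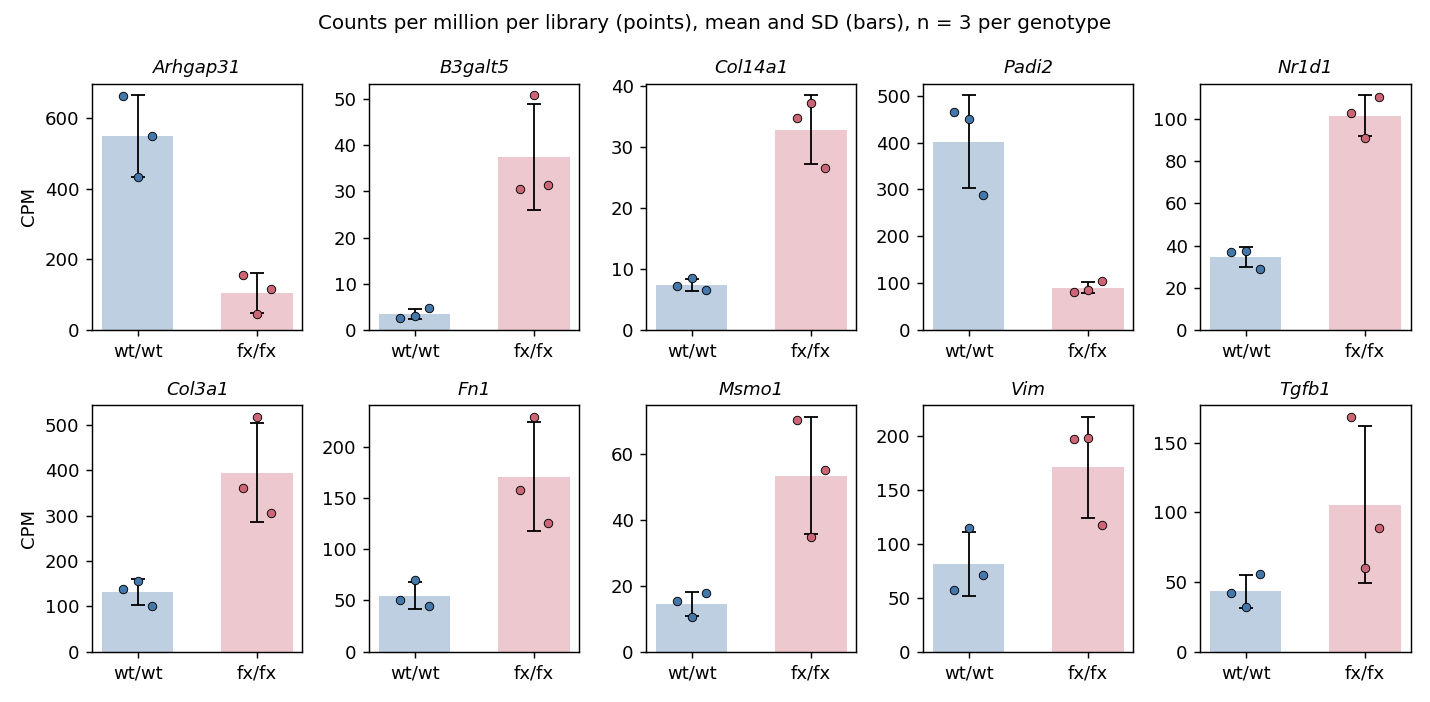
Counts per 1000000 counts (CPM, vertical axes, each starting at 0) of 10 genes in wt/wt and fx/fx tumors, with points for the 3 libraries per genotype, bars for the mean and error bars for the SD. Arhgap31 lies between 433 and 664 CPM in wt/wt and between 44.1 and 156 CPM in fx/fx, and the 10 genes shown all have an edgeR adjusted p above 0.05.

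Across the transcriptome, fx/fx tumors had higher levels of matrix, fibroblast, adipocyte, mast cell and cholesterol synthesis genes, and lower levels of ribosomal protein genes, by camera with the preset correlation. With an estimated correlation 0 lists passed (smallest adjusted p = 0.361). Ribosomal protein genes were well below wt/wt in fx1 only, with a mean log2 CPM relative to wt/wt of -0.98. This mean was -0.15 in fx2 and -0.18 in fx3, against -0.16 in wt1. B3galt5, a galactosyltransferase of glycan synthesis, measured 3.42 ± 1.15 CPM in wt/wt and 37.5 ± 11.5 CPM in fx/fx (n = 3 each), 11-fold higher. Col14a1, a fibril-associated collagen, was 4.44-fold higher, at 7.40 ± 0.955 against 32.8 ± 5.62 CPM. Padi2, a peptidylarginine deiminase, was 4.43-fold lower, at 401 ± 99.3 CPM in wt/wt and 90.5 ± 12 CPM in fx/fx. Nr1d1, a transcriptional repressor of the circadian clock, was 2.95-fold higher, at 34.4 ± 4.69 against 101 ± 9.73 CPM.

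These 4 genes had the smallest p of all genes tested, with edgeR adjusted p = 0.150 for each, and did not pass. Among the next by p were Alpl (log2 fold change -1.72), Fndc1 (2.20), Arhgef19 (-1.62), Entpd2 (-1.42) and Sorcs2 (3.36), with SEs between 0.19 and 0.45 and an edgeR adjusted p of 0.153. Alpl encodes tissue-nonspecific alkaline phosphatase, Arhgef19 a guanine nucleotide exchange factor and Entpd2 an enzyme that degrades extracellular nucleotides. All of these genes were separated between the genotypes. Without the filter on low counts edgeR called all of them, with adjusted p from 0.00245 (B3galt5) to 0.0456 (Sorcs2), and also Col3a1, Fn1, Itgav, Msmo1 and Hopx, which are named below. Padi2, Alpl and Arhgef19 lie on chromosome 4, whose genes were lower together in fx/fx tumors, as given with the chromosome values.

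Of 16752 genes tested, edgeR called 0 at an adjusted p under 0.05, with 2381 genes at an unadjusted p under 0.05 (1370 higher and 1011 lower in fx/fx) where chance gives 838. limma-voom called 0, with 3040 genes at an unadjusted p under 0.05. DESeq2 called 833 genes, 521 higher and 312 lower in fx/fx, of which 805 had an edgeR unadjusted p under 0.05. Genotypes did not overlap for 3295 genes, 19.7% of those tested, where chance gives 10%. Both chance values are averages, and single splits can lie far from them. Other splits of the libraries into groups of 3 gave between 295 and 1329 genes at an unadjusted edgeR p under 0.05. The DESeq2 count was 412 without wt1, 547 without wt3, 508 without fx1 and 1626 without fx2, where the balance turned to 744 higher and 882 lower.

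Among the DESeq2 calls, the largest increases were chosen after their values were seen. St8sia1, the synthase of the ganglioside GD3, measured 0.644 ± 0.539 CPM in wt/wt and 116 ± 109 CPM in fx/fx (n = 3 each; DESeq2 adjusted p = 2.1e-04, edgeR adjusted p = 0.185). Emb, which encodes the membrane glycoprotein embigin, was 58.3-fold higher, at 3.99 ± 3.23 against 233 ± 208 CPM (DESeq2 adjusted p = 3.5e-12). Comp, a cartilage matrix protein, was 30.8-fold higher, at 71.5 ± 80.7 against 2205 ± 2329 CPM. Ppp2r2b (31.6-fold), Angptl1 (27.3-fold), Unc79 (20.7-fold), Atp6v1c2 (19.1-fold), Fam89a (18.3-fold), Mycn (17.5-fold) and Ak1 (15.3-fold) completed the 10 highest. SDs were close to the mean in fx/fx for most of these genes, and none passed edgeR. In fx2, St8sia1 (1.34 CPM), Fam89a (1.42) and Mycn (0.43) lay close to the highest wt/wt library (1.24, 1.16 and 0.40), and single libraries carried Angptl1 (48.1 CPM in fx3) and Ppp2r2b (49.7 CPM in fx1). The DESeq2 calls of Comp, Unc79, Fam89a and Mycn were lost without fx1, those of Fam89a and Mycn also without wt1, that of Unc79 without wt2 or fx3 and that of Angptl1 without wt3.

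The 10 lowest, chosen in the same way, were led by Sec14l4 (28.2-fold lower), Ripply1 (13.3-fold) and Rab26 (11.9-fold). Sfmbt2, a Polycomb group gene, was 11.7-fold lower, at 6.35 ± 1.66 CPM in wt/wt and 0.530 ± 0.585 CPM in fx/fx (n = 3 each; DESeq2 adjusted p = 3.4e-05). Traf1, an adaptor of tumor necrosis factor receptors, was 8.96-fold lower, at 55.9 ± 18.3 against 6.23 ± 3.77 CPM (DESeq2 adjusted p = 1.0e-06, edgeR adjusted p = 0.153). Hopx, a homeodomain-only protein, was 7.26-fold lower, at 12.9 ± 5.79 against 1.76 ± 0.577 CPM. Psd2 (9.27-fold lower), Ggt6 (8.24-fold), Extl1 (7.73-fold, on chromosome 4) and Inha (6.44-fold) were the others. A single wt/wt library carried the level of 4 of these: Sec14l4 measured 26.3 CPM in wt3, and Rab26, Psd2 and Inha 41.2, 65.3 and 17.6 CPM in wt2. Their wt/wt values were 11.1 ± 13.4, 18.6 ± 19.6, 28.8 ± 31.6 and 8.04 ± 8.24 CPM (n = 3 each). Psd2 lost its DESeq2 call without wt2, Inha without wt2 or fx1 and Ripply1 without wt3.

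As groups, 20 of the 44 lists tested passed camera with the preset correlation, 19 higher and 1 lower in fx/fx, or 14 higher and 5 lower without fx2. With an estimated correlation 0 passed, and fry called 2 lists, mast cell and basal or myoepithelial markers. Over all genes tested, edgeR called 0 members of any list. Of 47 list members called by DESeq2 that the naming rule left out, between 14 (without wt1) and 32 (without fx3) kept the call with a library left out. The other splits of the 6 libraries into groups of 3 gave between 6 and 29 passing lists with the preset correlation. Counting the real split, 1 of 10 gave as small a camera p for interstitial matrix, fibroblast, mast cell, erythroid and cholesterol genes. The same held for the basal, focal adhesion and hormone-sensing lists. As small a p came from 2 of 10 splits for the mesenchymal, fatty acid, basement membrane and pericyte lists. It came from 3 for TGF-beta, ribosomal protein, immediate early, histone, endothelial and adipocyte genes, 4 for VEGF and 5 for hypoxia. Library scores of the basement membrane, hypoxia, fatty acid, VEGF, ribosomal protein, immediate early and histone lists, which passed, overlapped between the genotypes.

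Interstitial matrix genes rose, with a median log2 fold change of 1.34 (camera adjusted p = 1.1e-15; adjusted p = 0.36 with an estimated correlation). All 20 measured members were higher, 18 had an unadjusted edgeR p under 0.05, 18 passed adjusted over the list alone and 15 were called by DESeq2. The DESeq2 calls of Col1a1, Col5a1, Col5a2, Col6a1, Col6a2, Postn, Fbn1 and Bgn were lost without wt1 or wt3, and that of Thbs2 without wt1. Those of Col1a2, Col3a1, Dcn, Fn1, Lum and Mfap5 stayed with any library left out. Col3a1, a fibrillar collagen, measured 132 ± 27.9 CPM in wt/wt and 395 ± 109 CPM in fx/fx (n = 3 each; DESeq2 adjusted p = 1.6e-04, edgeR adjusted p = 0.153). Mfap5, a microfibril protein, was 2.88-fold higher, at 4.34 ± 0.597 against 12.5 ± 0.726 CPM (DESeq2 adjusted p = 8.2e-07). Basement membrane genes also rose (median 0.70; camera adjusted p = 1.3e-04; adjusted p = 0.36 with an estimated correlation), with 14 of 18 members higher, 9 of them at an unadjusted edgeR p under 0.05, 4 passing adjusted over the list alone and 4 called by DESeq2. Col18a1 was 2.24-fold higher and Lamc1 had a log2 fold change of 1.32, with DESeq2 adjusted p of 1.1e-03 and 5.2e-03. Fibroblast markers share 5 genes with the interstitial matrix list, and the 7 others had a mean log2 CPM relative to wt/wt of 1.06 in fx1, 1.43 in fx2 and 0.53 in fx3, against 0.18 or less in wt/wt.

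Mesenchymal genes rose (median 0.97; camera adjusted p = 3.1e-09; adjusted p = 0.36 with an estimated correlation). All 20 members were higher, 11 at an unadjusted edgeR p under 0.05, 9 passing adjusted over the list alone and 6 called by DESeq2. The DESeq2 calls of Twist1, Foxc2, Mmp14 and Loxl2 were lost without wt1 or wt3. For this list a split that mixed the genotypes gave a smaller camera p (7.7e-12) than the real one (2.1e-10). Fn1, fibronectin, measured 54.6 ± 13.2 CPM in wt/wt and 171 ± 52.9 CPM in fx/fx (n = 3 each; DESeq2 adjusted p = 2.1e-04), and Tnc, tenascin C, was 3.33-fold higher although it lies on chromosome 4. Fibroblast markers, with a median of 1.42, were higher in the same tumors. Among single genes fixed for this question, Vim measured 81.0 ± 29.5 against 171 ± 46.5 CPM (log2 fold change 1.07, SE 0.32; edgeR adjusted p = 0.227, DESeq2 adjusted p = 0.066). Zeb2 (0.57, SE 0.44), Snai1 (0.96, SE 0.40) and Snai2 (0.78, SE 0.44), transcription factors that repress Cdh1, did not pass, with edgeR adjusted p between 0.337 and 0.608. Vim, Zeb2 and Snai1 lie on chromosome 2, whose median relative to wt/wt was 0.43 in fx2, 0.06 in fx1 and 0.08 in fx3. Snai1 was highest in fx2 (3.67 CPM, against 3.05 in fx1 and 1.82 in fx3). Vim and Zeb2 were about as high in fx1 (197 and 20.2 CPM) as in fx2 (198 and 19.1 CPM). Cdh1, E-cadherin, measured 309 ± 41.9 against 371 ± 96.5 CPM and did not pass (log2 fold change 0.26, edgeR adjusted p = 0.677). Epithelial junction genes did not pass as a list, with a median of 0.09 over 25 members and camera adjusted p = 0.83.

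TGF-beta response genes rose (median 0.53; camera adjusted p = 9.2e-04; adjusted p = 0.37 with an estimated correlation), with 17 of 21 members higher, 7 of them at an unadjusted edgeR p under 0.05, and 1 passing adjusted over the list alone. Scores were 0.57 in fx1 and 0.50 in fx2, but 0.085 in fx3, close to wt3 at 0.045. Fibroblast scores (1.34, 1.72 and 0.79 in fx1, fx2 and fx3) and endothelial scores (1.09, 0.93 and 0.15) were also lowest in fx3 among fx/fx. DESeq2 called Smad7, Thbs1 and Bambi higher and Ltbp2 lower. Smad7 and Bambi encode inhibitors of the pathway. Smad7 measured 19.2 ± 3.71 CPM in wt/wt and 44.9 ± 10.1 CPM in fx/fx (n = 3 each; DESeq2 adjusted p = 3.8e-03, edgeR adjusted p = 0.164), and Thbs1 was 2.58-fold higher. The DESeq2 call of Smad7 was lost without wt1, that of Thbs1 without wt1, wt3 or fx1, that of Bambi without wt1, wt2, fx1 or fx3, and that of Ltbp2 with any library other than fx2 left out. Tgfb1 itself measured 43.3 ± 11.8 against 106 ± 56.2 CPM and did not pass (log2 fold change 1.29, edgeR adjusted p = 0.235, DESeq2 adjusted p = 0.062). Focal adhesion and integrin genes rose (median 0.36; camera adjusted p = 0.010; adjusted p = 0.36 with an estimated correlation), led by Itgav, 2.69-fold higher (DESeq2 adjusted p = 9.9e-04), with 1 of 28 members passing adjusted over the list alone; Tns1 had a log2 fold change of 0.86. Tln1, which couples integrins to actin, had a log2 fold change of -0.24 and did not pass (edgeR adjusted p = 0.701). It lies on chromosome 4, whose genes were lower together in fx1 and fx3.

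Cdc42 and Rac1, the GTPases that CdGAP acts on, did not pass. Cdc42 measured 413 ± 46.7 CPM in wt/wt and 321 ± 102 CPM in fx/fx (n = 3 each; edgeR adjusted p = 0.569) and lies on chromosome 4, and Rac1 measured 337 ± 55.9 against 348 ± 48.6 CPM (edgeR adjusted p = 0.945). The other Arhgap family genes (median 0.11) and ErbB signalling genes (median 0.16) did not pass camera, with adjusted p of 0.30 and 0.19. Erbb2 measured 1664 ± 705 against 2582 ± 1045 CPM (log2 fold change 0.63, edgeR adjusted p = 0.546), and counts per gene cannot tell transgene reads that align there from those of the native gene.

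Cholesterol synthesis genes rose, with all 20 members higher and a median of 0.71 (camera adjusted p = 1.5e-09; adjusted p = 0.36 with an estimated correlation). Of these, 10 had an unadjusted edgeR p under 0.05, 9 passed adjusted over the list alone and 7 were called by DESeq2. Hmgcs1 measured 51.9 ± 6.49 CPM in wt/wt and 118 ± 18.9 CPM in fx/fx, and Msmo1 measured 14.5 ± 3.72 against 53.4 ± 17.8 CPM (n = 3 each; DESeq2 adjusted p = 6.8e-04 and 8.0e-05, edgeR adjusted p = 0.153 for both). Fatty acid synthesis genes rose (median 0.43; camera adjusted p = 0.015; adjusted p = 0.37 with an estimated correlation), with 10 of 16 members higher and 3 passing adjusted over the list alone. Me1, malic enzyme, was 2.24-fold and Acss2, acetyl-CoA synthetase, 2.25-fold higher, both called by DESeq2 (adjusted p = 0.013 and 0.022). Me1 lost this call without wt1, wt2 or fx1, and Acss2 with any wt/wt library left out. Adipocyte markers (median 2.44) were higher in the same tumors, and Acss2 was highest in fx2 (46.1 CPM, against 27.6 in fx1 and 25.1 in fx3), which had the highest adipocyte score (3.02). Acss2 also lies on chromosome 2, where genes from 140 to 160 Mb had a median of 0.40 in fx2, 0.03 in fx1 and 0.06 in fx3, relative to wt/wt. Hypoxia and glycolysis genes rose (median 0.32; camera adjusted p = 0.027; adjusted p = 0.72 with an estimated correlation), with 17 of 23 members higher and 3 passing adjusted over the list alone. Gapdh was 2.02-fold higher (DESeq2 adjusted p = 9.7e-03) and Pgam1 1.51-fold higher (0.062), and Gapdh lost its call without wt1 or wt3. DESeq2 also called Adm (3.11-fold) and Pfkfb3 (3.33-fold) higher, but not without wt1, wt3 or fx2, nor Adm without fx3 or Pfkfb3 without fx1. The fatty acid and hypoxia lists no longer passed without wt3 or without fx2, nor did the hypoxia list without wt1.

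Markers of several non-epithelial cell types rose. Fibroblast markers had a median of 1.42 (camera adjusted p = 4.1e-09; adjusted p = 0.36 with an estimated correlation), with 11 of 12 members higher, 10 passing adjusted over the list alone and 7 called by DESeq2. Of these calls, Dcn, Lum, Col1a1, Col3a1 and Mfap5 were also counted with the interstitial matrix genes. The others were Dpt and Clec3b, and Clec3b lost its call without wt1. Adipocyte markers had a median of 2.44 (camera adjusted p = 1.2e-06; adjusted p = 0.43 with an estimated correlation), with 4 of 12 passing adjusted over the list alone. Fabp4, a fatty acid carrier, measured 18.7 ± 6.09 CPM in wt/wt and 61.0 ± 34.1 CPM in fx/fx (n = 3 each; DESeq2 adjusted p = 9.3e-03), and the adipokine Cfd was 6.65-fold higher. DESeq2 also called Cidec and Retn higher (log2 fold changes 2.59 and 3.08). Its calls were lost for Fabp4 without wt2 or wt3, for Cidec without wt3 or fx2, and for Retn with wt2 or any fx/fx library left out. Mast cell markers had a median of 2.17 (camera adjusted p = 3.0e-06; adjusted p = 0.36 with an estimated correlation; fry adjusted p = 0.034), and all 5 passed adjusted over the list alone. The mast cell proteases Cma1 and Mcpt4 stayed low, at 1.18 ± 0.186 and 1.27 ± 0.295 CPM in fx/fx (n = 3 each) against 0.236 ± 0.0325 and 0.280 ± 0.0507 CPM in wt/wt.

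Endothelial markers rose as well (median 0.67; camera adjusted p = 2.6e-06; adjusted p = 0.50 with an estimated correlation), with all 16 members higher and 1, Vwf, passing adjusted over the list alone. Scores were 1.09 in fx1 and 0.93 in fx2, but 0.15 in fx3, level with wt1 at 0.14. Vwf was 3.54-fold higher (DESeq2 adjusted p = 1.6e-03) and Eng had a log2 fold change of 0.81. Pericyte markers rose (median 0.92; camera adjusted p = 5.5e-05; adjusted p = 0.37 with an estimated correlation), with 4 of 9 passing adjusted over the list alone, led by Cspg4 at 2.51-fold, while Abcc9 had a log2 fold change of 0.92. Erythroid markers rose (median 1.32; camera adjusted p = 1.3e-04; adjusted p = 0.37 with an estimated correlation), with 4 of 5 passing adjusted over the list alone; Hba-a1 was 3.17-fold and Hbb-bs 2.66-fold higher, the latter not called by DESeq2 without fx1. VEGF and angiogenesis genes rose (median 0.52; camera adjusted p = 0.012; adjusted p = 0.66 with an estimated correlation), with 0 of 20 called by edgeR over the list alone or by DESeq2 and 2 at an unadjusted edgeR p under 0.05, Aplnr (0.87) and Tek (0.77). Vegfa did not pass (log2 fold change 0.55, edgeR adjusted p = 0.629). Scores were 0.70 in fx1, 0.77 in fx2 and -0.21 in fx3, the last below the wt/wt libraries (-0.11 to 0.11). The VEGF list no longer passed without wt3, without fx1, without fx2 or without the chromosome 4 genes.

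Basal and myoepithelial markers rose (median 0.97; camera adjusted p = 1.3e-04; adjusted p = 0.36 with an estimated correlation; fry adjusted p = 0.041), with 9 of 10 members higher and 3 passing adjusted over the list alone. Krt5, a basal keratin, measured 0.287 ± 0.114 CPM in wt/wt and 1.34 ± 0.513 CPM in fx/fx (n = 3 each; DESeq2 adjusted p = 6.3e-03), and Cnn1 was at 0.310 ± 0.103 against 0.825 ± 0.106 CPM. Hormone-sensing luminal markers rose (median 0.47; camera adjusted p = 0.028; adjusted p = 0.36 with an estimated correlation), with Esr1, the estrogen receptor, at 5.69 ± 3.38 against 16.9 ± 4.67 CPM (DESeq2 adjusted p = 0.031) and Wnt4 below 1 CPM in both genotypes. The DESeq2 call of Esr1 was lost without wt2, wt3, fx1 or fx3, and that of Krt5 without fx1 or fx3. The hormone-sensing list no longer passed without fx2 or without the chromosome 4 genes. Luminal progenitor markers (median -0.21; camera adjusted p = 0.47) and milk and alveolar markers (median 0.04, mean -0.22; camera adjusted p = 0.25) did not pass.

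Ribosomal protein genes fell, with all 30 members lower and a median of -0.33 (camera adjusted p = 3.0e-06; adjusted p = 0.66 with an estimated correlation). Their mean log2 CPM relative to wt/wt was -0.98 in fx1, -0.15 in fx2 and -0.18 in fx3, against -0.16, 0.10 and 0.06 in wt1, wt2 and wt3, so only fx1 lay well below the wt/wt libraries. The members with the smallest p, Rps20 (-0.82) and Rpl11 (-0.81), both lie on chromosome 4. Adjusted over the list alone, edgeR called 0 of the 30, with 2 at an unadjusted p under 0.05 and 0 called by DESeq2. Immediate early genes rose (median 0.19; camera adjusted p = 0.040; adjusted p = 0.65 with an estimated correlation), with Ccn1 2.03-fold and Egr1 1.87-fold higher, both called by DESeq2. Egr1 lost this call with any library other than wt2 left out, and without the chromosome 4 genes. Replication-dependent histone genes rose (median 1.16; camera adjusted p = 0.026; adjusted p = 0.64 with an estimated correlation), with Hist1h1d at 2.57 ± 1.70 against 10.8 ± 7.39 CPM (n = 3 each; DESeq2 adjusted p = 0.039) and a log2 fold change of 2.31 for Hist1h4d. Scores were 1.81 in fx1 and 1.29 in fx3, but -0.19 in fx2, below wt2 at 0.29 and wt3 at 0.28, and Hist1h1d lost its DESeq2 call without wt1, wt2, fx1 or fx3. The immediate early list no longer passed without wt1, wt3 or fx2 or with protein-coding genes only, and the histone list without wt1, fx1 or fx3.

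Apart from mast cell markers, immune lists did not pass, nor did proliferation lists. Macrophage markers had a median of 0.02 (camera adjusted p = 0.70), T cell markers -0.19 (0.88), NK and cytotoxic markers -0.62 (0.67), B and plasma cell markers 0.79 (0.077) and dendritic cell markers 0.10 (0.33). Interferon response genes had a median of -0.73 (0.19), with library means between 2.21 in wt1 and -2.42 in fx3 relative to wt/wt. Antigen presentation genes had a median of 0.10 (0.060) and NF-kB inflammatory genes 0.23 (0.16). G2/M genes had a median of -0.26 (0.10), S phase genes -0.14 (0.22) and p53 target genes -0.16 (0.39). Wnt pathway genes had a median of 0.77 (0.052), Notch pathway genes 0.35 (0.23), nuclear OXPHOS genes 0.06 (0.56) and mitochondrially encoded genes 0.24 (0.33). Unfolded protein response genes had a median of 0.03 (0.83), heat shock genes -0.02 (0.70) and Schwann cell markers 0.44 (0.68). Neutrophil, skeletal muscle and keratinocyte markers, with 4, 3 and 3 measured members and medians of 0.43, 0.77 and -0.60, were too small to test. Leaving out a library made some of these lists pass: antigen presentation genes without wt1, fx1 or fx3, and B and plasma cell markers without wt1 or fx3. Interferon response genes passed without wt2 or fx2, G2/M genes without wt3, fx2 or fx3, and Wnt pathway genes without wt3 or fx3. In a single setting, dendritic cell markers passed without wt1, NF-kB genes without wt2, skeletal muscle markers without fx1, p53 target and milk and alveolar genes without fx2, and S phase genes and macrophage markers without fx3.

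**Figure D2:**
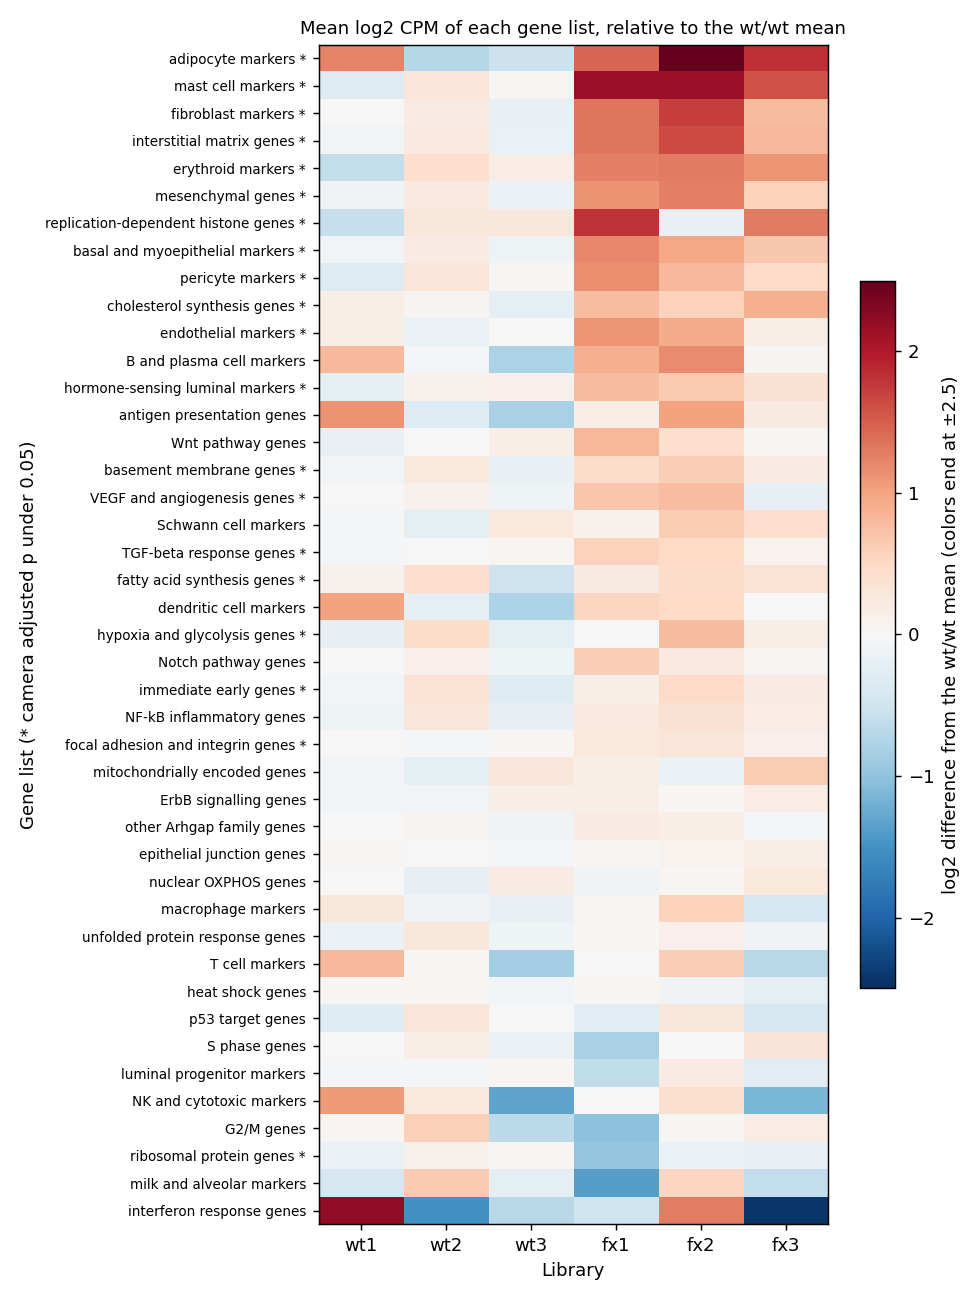
Mean log2 CPM of the gene lists reported here (rows) in each library (columns), relative to the wt/wt mean, in red above and blue below it, with a star for lists past camera with the preset correlation. Interstitial matrix genes lie at 1.34, 1.63 and 0.82 in fx1, fx2 and fx3, and interferon response genes range from 2.21 in wt1 to -2.42 in fx3.

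Genes on chromosome 4 were lower as a group in fx/fx tumors, a comparison made after the data were seen. The median over 646 genes, relative to the wt/wt mean, was -0.70 in fx1, -0.12 in fx2 and -0.82 in fx3, and 0.02, -0.07 and 0.05 in wt1, wt2 and wt3. In fx1 and fx3 the whole chromosome was lower, while in fx2 the median was -0.046 below 120 Mb and -0.61 from 140 Mb on, though not up to the end, since its bin from 155 Mb lay at -0.13 and those between 140 and 150 Mb at -0.85 or lower. Padi2, Alpl and Arhgef19 all start between 135 and 150 Mb, where the medians of all 3 fx/fx libraries were below -0.4. Of the DESeq2 calls lower in fx/fx, 96 of 312 (30.8%) lay on chromosome 4, which held 6.03% of the genes with an adjusted p (Fisher's exact test over genes, p = 1.4e-42). Genes are not independent replicates, and the exact 2-sided permutation test of the 6 library medians gave p = 0.1, the smallest possible.

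Chromosome 10 had a median of -0.61 in fx1, chromosome 2 of 0.43 in fx2 and chromosome 14 of 0.24 in wt2. Chromosome 1 had medians of 0.10, -0.32 and 0.17 in wt1, wt2 and wt3, and between 0.22 and 0.53 in the fx/fx libraries. From 120 to 140 Mb on it, wt1 (0.42) lay level with fx1 (0.42) and above fx2 (0.35) and fx3 (0.38). There wt2 lay at -0.59, which lowers the wt/wt mean that serves as 0, so such shifts were not confined to fx/fx. The chromosome 1 shift was over positions from 80 Mb on, which include Lamc1 and Angptl1 but not Col3a1 or Fn1. On chromosome 11, the 200 genes from 60 to 80 Mb, where Ggt6 lies, had medians of -0.62 in fx1, -0.04 in fx2 and -0.83 in fx3, and between -0.06 and 0.08 in wt/wt. Genotypes did not overlap for 2 of the 20 chromosomes, 1 and 4, which is as many as chance gives. Without the chromosome 4 genes, edgeR still called 0 genes, DESeq2 called 694 and 18 lists passed.

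**Figure D3:**
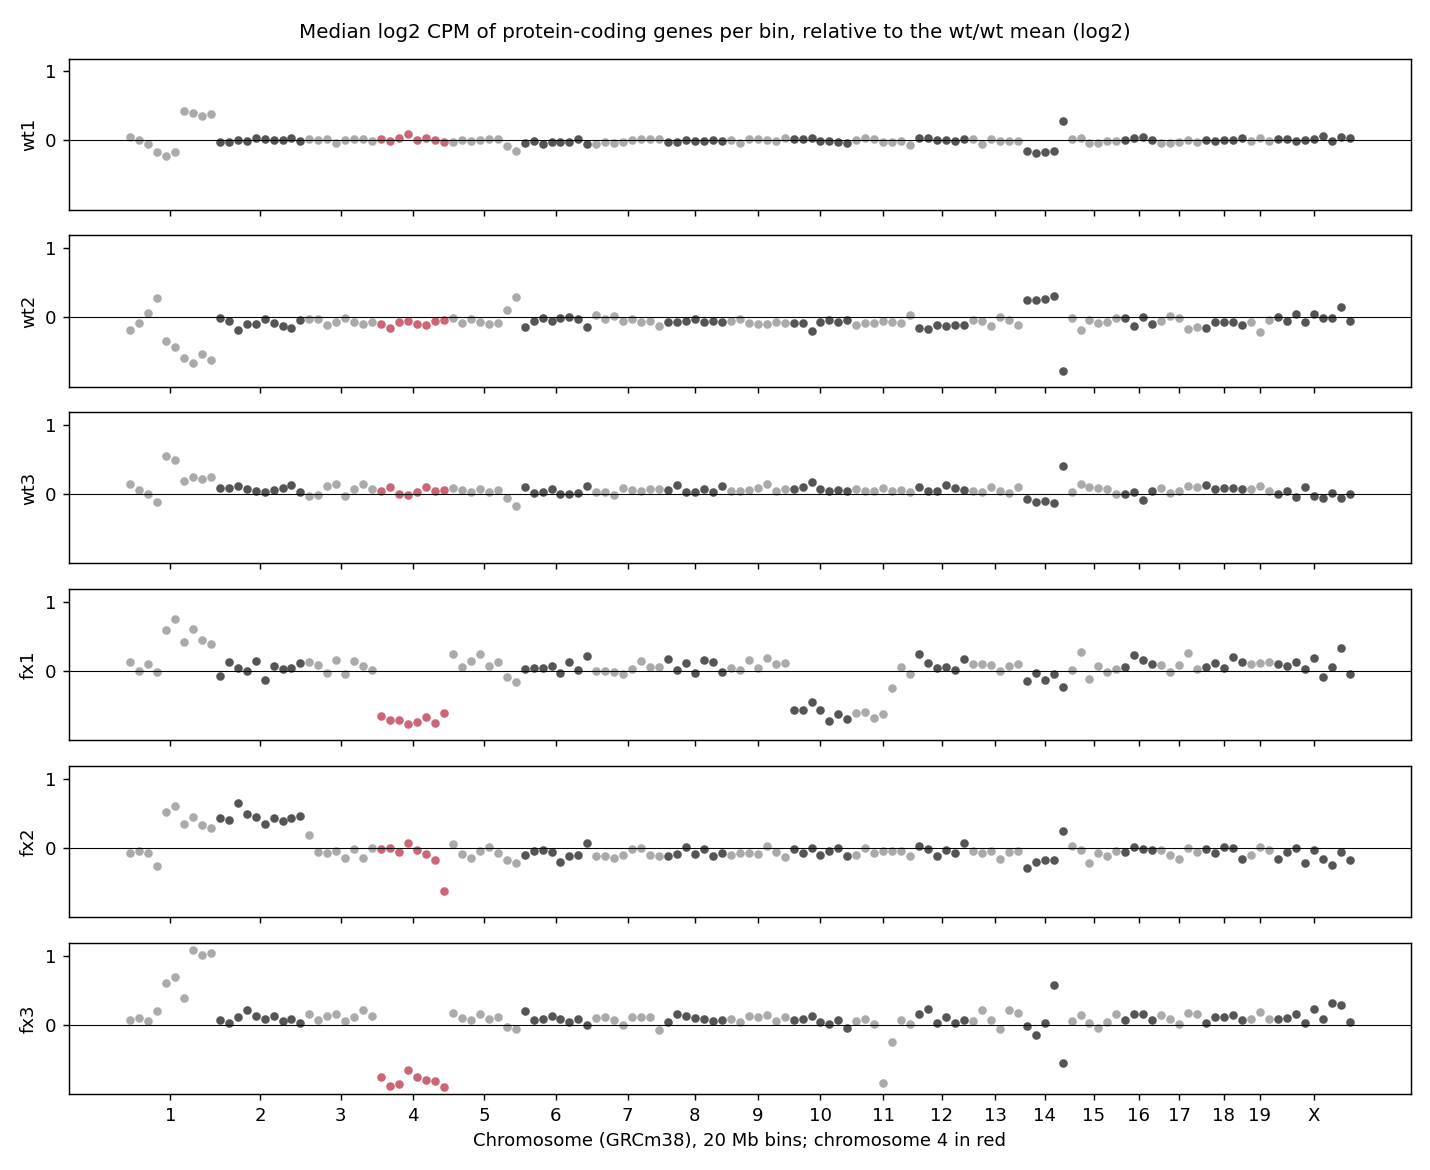
Median log2 CPM of protein-coding genes per 20 Mb bin (vertical axis, relative to the wt/wt mean) along the chromosomes (horizontal axis), with a panel per library and chromosome 4 in red. Chromosome 4 lies near 0 in the wt/wt libraries, at medians of -0.70 and -0.82 in fx1 and fx3, and is lower in fx2 only over a distal part.

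Genes near Arhgap31 were compared because a targeted allele can carry flanking sequence of another strain. Within 10 Mb, edgeR called 0 of 135 genes against 0 of 16616 elsewhere, so the test had no calls to compare (Fisher's exact p = 1). DESeq2 called 8 of 145 (5.52%) against 4.62% of other genes (Fisher's exact p = 0.55), and the median log2 fold change of the neighbours was 0.11.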

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

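The alternatives to the DESeq2 count and to the chromosome 4 median, and leaving out chromosome 4 genes, were chosen after seeing the data. The edgeR count stayed at 0 with DESeq2 size factors, protein-coding genes only, robust=FALSE, both other thresholds and without chromosome 4 genes, and limma-voom with quality weights also gave 0. Without the filter on low counts edgeR called 38 genes (23 higher, 15 lower), all of which had also been tested with the filter and were called by DESeq2; the cause was not tested. The DESeq2 Wald test called 833. With a library left out the edgeR count ranged from 0 to 2, the 2 being Gjb1 and St3gal4 without fx2. Arhgap31 had a DESeq2 log2 fold change of -2.40, which passed, while its value ranged from -2.80 (without fx1) to -2.02 (without fx2) and did not pass in edgeR. The number of passing lists was 0 with an estimated correlation and 2 with fry, and between 18 and 25 with a library left out; Wnt pathway genes also passed with DESeq2 size factors and antigen presentation genes without the filter. The DESeq2 count ranged from 412 (without wt1) to 1626 (without fx2), with 547 without wt3 and 508 without fx1; of 58 named genes called by DESeq2, 46 to 57 kept their call across these and the other DESeq2 settings apart from the filter, which kept all 58. The chromosome 4 difference of -0.55 kept its sign in all settings run, from -0.39 without fx3 to -0.76 without fx2.

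With the replicate number as a replicate block, edgeR called 0 genes and camera 22 lists (antigen presentation genes and B and plasma cell markers were gained). DESeq2 called 751 genes, of which 577 were among its 833 main calls. Of the 58 named genes called by DESeq2, 57 kept the call and Acss2 lost it. Of the 47 other list members, 39 kept it, and Bambi, Twist1, Foxc2, Thbs2, Cpa3 and Tpsb2 were among those that lost it. Arhgap31 had a log2 fold change of -2.54. Same-numbered libraries deviated from their genotype means with correlations of -0.085, -0.095 and 0.057. Expression thus showed no sign of pairing by number, though so few pairs cannot exclude it and the labels do not say. Windows of 5 and 20 Mb around Arhgap31 also held 0 edgeR calls. No called value changed sign; 4 uncalled gene values and 23 uncalled list directions did. At these depths edgeR recovered 53.7% of simulated 4-fold changes, so a count of 0 does not exclude changes of that size in single genes.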

Other observations

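The genes and tests of this part were chosen after their values were seen. Of the ErbB signalling genes, a list that did not pass, DESeq2 called Egf, Erbb4 and Tgfa. Egf measured 179 ± 6.82 CPM in wt/wt and 50.9 ± 43.0 CPM in fx/fx (n = 3 each; log2 fold change -1.82, DESeq2 adjusted p = 0.028), and the receptor Erbb4 measured 86.1 ± 29.0 against 40.2 ± 5.80 CPM (DESeq2 adjusted p = 0.019). Tgfa, another ligand of the epidermal growth factor receptor, was 2.41-fold higher (DESeq2 adjusted p = 8.9e-03). None of the 3 passed edgeR, and DESeq2 calls were lost without wt1, wt2, wt3 or fx2 for Egf, without wt2, fx1 or fx3 for Erbb4 and without wt1, wt2 or fx1 for Tgfa.

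The epithelial genes Cldn4 (7.20-fold) and Krt19 (2.25-fold) and the macrophage gene Cd163 (2.66-fold) were also higher by DESeq2, although their lists did not pass. Cldn4 measured between 4.54 and 12.4 CPM in wt/wt and 57.6 ± 69.0 CPM in fx/fx (n = 3 each), and fx1, at 137 CPM, carried most of it. The DESeq2 call was lost without wt1, wt3 or fx1 for Cldn4 and without wt1, wt3 or fx3 for Krt19. Spp1, osteopontin, measured 6920 CPM in fx1 against 83.7 and 79.5 CPM in fx2 and fx3 and between 9.92 and 18.6 CPM in wt/wt. Xist measured 201 CPM in fx1 and between 726 and 1459 CPM in the other 5 libraries, while the chromosome X median of fx1 was 0.07.

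Chromosome 4 genes were lower in fx/fx tumors, with a log2 difference of -0.55 (pooled SD 0.27). A correction for GC content and transcript length left -0.55, and setting chromosome 4 against the other chromosomes of each library left -0.57 (pooled SD 0.33), which argues against either bias and against scaling as the whole cause. An effect of the fx/fx genotype on the whole chromosome stays open, since the fx2 median below 120 Mb, -0.046 where the SD of the wt/wt medians was 0.06, is that of a single library. In fx1 and fx3, 26 of 26 bins of 5 Mb were below -0.4, against 4 in fx2 and 0 in any wt/wt library, but the bound was set on this profile, so the count does not test a loss of chromosome 4 copies in the tumor cells. DNA was not analysed here, and such a loss, linked to genotype or not, cannot be told apart from an effect on expression.

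Fibroblast, matrix and mast cell markers were higher in fx/fx tumors. If a lower share of tumor cells had raised every other cell type alike, macrophage markers would have followed. The fibroblast minus macrophage score was higher in fx/fx by 1.22 (log2, SD 0.30 in wt/wt and 0.075 in fx/fx). Its exact permutation p was 0.1, the smallest possible. Both lists were picked after their values were seen, and 3 of the 15 macrophage markers lie on chromosome 4, so the score does not decide the question. It shows only that these lists did not rise alike, since the macrophage score differed by 0.06 (pooled SD 0.40) and the T cell score by -0.03 (pooled SD 0.75). Surrounding fat and connective tissue may have been taken along with the fx/fx tumors: the adipocyte score was higher by 2.10 (pooled SD 0.96), and wt1, at 1.25, lay close to fx1, at 1.46, without a higher matrix score. Such tissue cannot be told apart from an effect of genotype, because a difference in tissue taken would separate the same samples. An effect of CdGAP loss on the tumor stroma therefore stays an untested hypothesis.

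Nr1d1 and Dbp, both under circadian control, were higher in fx/fx tumors by 1.56 and 1.29 (log2). A difference in the time of day at collection may be considered. Nr1d2, Tef, Hlf, Per1, Per2, Per3 and Ciart, which the same clock drives, had a median of 0.030 (SD over the genes 0.55). Nr1d1 and Dbp were picked for their own values, so a smaller median of other clock genes does not decide the question. Per2 was separated between the genotypes and higher by 0.81. Arntl (-0.25), Npas2 (-1.01) and Cry1 (-0.63), which peak at other times, were lower without passing, while Clock (0.30) was higher without passing. A contribution of collection time therefore stays open. Per3 (-0.74) lies on chromosome 4 and Per2 on the shifted part of chromosome 1. No biological explanation was tested.

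The 6 libraries can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 2381 genes at an unadjusted edgeR p under 0.05 and the highest other split 1329, so 1 of 10 splits gave as many. For edgeR adjusted p the count was 0 in 10 of 10 splits. DESeq2 called 833 genes in the real split and at most 236 in another, so 1 of 10 gave as many. For gene lists the real split gave 20 and the highest other 29, and 3 of 10 splits gave at least as many.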
